A study of Mus musculus with 2 samples.

How the data were processed

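H3K9ac was measured by chromatin immunoprecipitation and sequencing in the hindbrain of mouse embryos at embryonic day 11.5 (strain B6NCrl, both sexes), in 2 biological replicates of 109 and 88 pooled embryos, per the labels. The labels assign both samples to the same tissue and age, so they form 1 group. Both pools carry the same strain donor entry, and p-values here are over genes, regions or random placements and never over embryos.

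The deposited files were 4 lists of peaks in the narrowPeak layout with coordinates in the mm10 build, per the labels and the deposited text notes. Peaks had been called by the authors on each replicate alone and on the alignments of both together, and each of these lists was also derived from 2 further files shared by all of them, whose roles are not given. The replicated list had been derived by the authors from the pooled list and both replicates' lists, per the deposited notes, but the rule for keeping a peak is not given in the sources used here. The aligner, the peak caller, its control and its thresholds are likewise not given in the sources used here. The fold enrichment of each peak is a linear ratio as deposited by the authors, taken as enrichment over background. The p-value and q-value of each peak were deposited as -log10 values. The lowest -log10 p in the lists was close to 2, so many weak peaks are included, and of the peaks of replicate 1, replicate 2, the pooled and the replicated list, 77.6%, 71.6%, 74.6% and 86.6% had a -log10 q of 2 or more. The files hold no read counts, so the depth of each library is unknown, no interval that needs it is given, and differences in the number of peaks cannot be separated from differences in depth.

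Peaks on chromosomes 1 to 19, X and Y were used, which left out 8, 6, 6 and 6 peaks of the 4 lists. The lists covered 34.3, 25.1, 27.7 and 26.0 Mb. The pooled list exceeded the replicated one by 7355 peaks. Genes came from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, with 21938 protein-coding genes on these chromosomes, and sequence came from GRCm38. Coordinates are 1-based. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.

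Replicate peaks counted as shared at an overlap of 1 bp. Background overlaps came from 100 random placements of a list on the same chromosomes, outside assembly gaps. A gene counted as marked where a replicated peak overlapped 1 kb either side of any of its annotated transcript starts, and its fold was the highest among those peaks. Breadth was the base pairs covered within 5 kb of an annotated start, taken at the start with the most coverage. Genes with more annotated starts therefore had more windows to choose from, which was not matched. A distal peak lay over 5 kb from every annotated start and was assigned to the nearest gene. Coverage up- and downstream of the 5'-most start was compared over 2 kb by sign flips over genes. CpG content was the ratio of observed to expected CpG within 1 kb of the 5'-most start. Domains were replicated peaks joined over gaps of up to 1 kb.

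The 20 gene lists were fixed before the data were examined, with the tests, the rule for named genes and all alternatives not described as added later. They comprised 3 groups of Hox genes, hindbrain and rhombomere patterning, neural progenitors, dorsoventral progenitor domains, hindbrain neuron subtypes, pan-neuronal genes, forebrain and midbrain transcription factors, mesenchyme and neural crest, endothelium, blood and microglia, mature glia, differentiated non-neural tissues, germline, olfactory receptors, cytoplasmic ribosomal proteins, cell cycle, housekeeping, and lysine acetyltransferases and deacetylases. Olfactory receptors and ribosomal proteins were taken by symbol pattern and the others by name. No gene was in more than 1 list. Marking was tested by a two-sided Fisher's exact test against all other protein-coding genes. Fold and breadth were tested in lists with 5 or more marked genes by two-sided permutation of medians with 100000 resamples, and distal peaks against 10000 random lists matched on the length of sequence nearest to each gene. Marking was also set against 10000 random lists matched on the decile of CpG content. All p-values were adjusted over the lists by the Benjamini-Hochberg method at a threshold of 0.05. Values below the smallest number the software represents, as for the marking of olfactory receptors, are not printed.

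The text names the 10 genes of highest fold at a start site, the 10 genes with the widest domains, the 3 strongest marked and the first 2 unmarked members by symbol of each list, Hox genes, the 5 strongest distal peaks and the 3 strongest peaks of each replicate alone. Genes named for their number of distal peaks were chosen after the values were seen.

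Alternatives changed the overlap rule, the window (500 bp, 2 kb), the peak list (pooled, a -log10 q of 2 or more, the upper 50% by fold, each replicate alone), the start sites (5'-most only), the background, the breadth and distal distances and the joining gap. Restriction to replicated peaks overlapped in both replicates' lists, and to peaks that reach the start of 1 gene only, was added after the data were seen. The procedures were tested on simulated data. Of 200 random lists of 25 genes, 5% were called for marking, 3.5% for strength and 0.5% for distal peaks at an unadjusted p of 0.05. All 25 planted marked genes and 21 of 21 planted distal genes were found. A planted fold ratio of 2 between a list of 25 genes and the rest came back as 2.35. A planted overlap of 49.8% came back as 49.9%, and a planted difference of 200 bp between the sides of the start came back as 199.994 bp over 8083 genes.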

Results

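Acetylation of histone H3 at lysine 9 (H3K9ac), a mark found at active promoters, was mapped by chromatin immunoprecipitation and sequencing in the hindbrain of mouse embryos at embryonic day 11.5. The embryonic hindbrain gives rise to the cerebellum, pons and medulla and is at this age divided along its length into rhombomeres. There was 1 group of 2 biological replicates, which pooled the hindbrains of 109 and 88 embryos of both sexes from the B6NCrl strain. The deposited data were 4 lists of peaks in the mm10 genome build. Replicate 1 alone gave 57125 peaks, replicate 2 alone gave 49113, and the pooled reads of both gave 38448. A replicated list of 31093 peaks had been drawn by the authors from the pooled list. The number of reads behind each list is unknown, because the files hold no read counts. With a single tissue and age there was no comparison between conditions. The questions asked were how far the replicates agreed and where in the genome, and at which genes, the mark lay. Fold enrichments throughout are the authors' own values per peak. They describe and rank peaks within a list, and values given as mean ± SD (n = 2) are over the replicates' own lists. Such an SD includes any difference in scale between those lists.

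Nearly all of the stronger H3K9ac peaks of one hindbrain pool were found again in the other pool, and those missing were typically weak and narrow. Of the 49107 peaks of replicate 2 on the numbered, X and Y chromosomes, 32654 (66.5%) overlapped a peak of replicate 1 by at least 1 bp. Of the 57117 such peaks of replicate 1, 27347 (47.9%) overlapped a peak of replicate 2. In the top 10% of peaks by fold the share was 100% in both lists, and in the lowest 10% it was 16.3% for replicate 1 and 38.7% for replicate 2. Over 26753 regions of the replicated list seen in both, the folds of the replicates ranked alike, with a Spearman's rho of 0.827 and a Pearson's r of 0.841 on log2 values. These correlations are across regions of 2 libraries, and regions are not independent replicates. Random placement of the second list on the same chromosomes gave mean overlaps of 2.36% for replicate 1 and 2.74% for replicate 2. None of the 100 placements reached the observed values (one-sided permutation p = 0.0099 for each, the smallest that 100 placements can give). Placements ignored that 44.9% and 52.2% of the peaks of replicates 1 and 2 lay within 1 kb of start sites. Lists sharing only that preference would also exceed this background. With a reciprocal overlap of 50% the shares were 33.7% and 39.1%. With the 24553 peaks of smallest p-value from each list they were 74.6% and 86.6%.

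**Figure D1:**
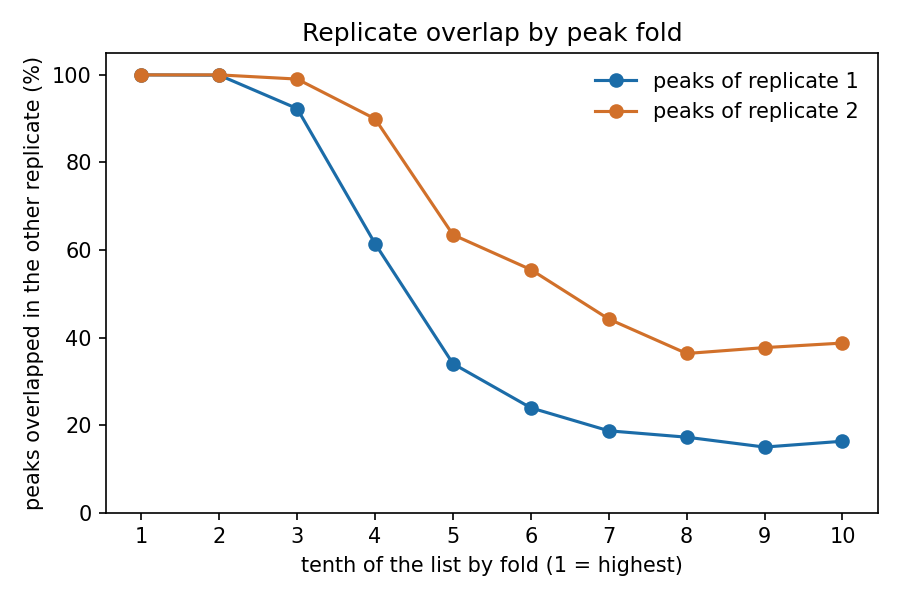
Agreement of the 2 replicates' peak lists, by the authors' fold enrichment. The share of peaks overlapped by the other replicate reached 100% in the strongest 10% of both lists and fell to 16.3% (replicate 1) and 38.7% (replicate 2) in the weakest, and folds of the 26753 shared regions had a Spearman's rho of 0.827.

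Peaks called in 1 replicate only were mostly away from promoters. Replicate 1 had 29770 of them (52.1% of its list), with a median width of 239 bp and a median fold of 3.17. Its shared peaks had a median width of 747 bp and a median fold of 6.34. Replicate 2 had 16453 peaks of its own (33.5%), with a median width of 201 bp and a median fold of 3.13, against 462 bp and 4.84 for its shared peaks. Transcription start sites lay within 1 kb of 22.3% and 17.2% of the unshared peaks of replicates 1 and 2, and of 69.6% and 69.9% of the shared ones. The strongest peak seen in replicate 1 alone had a fold of 10.96 and lay in an untranslated region of Slc6a17, a vesicular amino acid transporter, 0.091 kb from its start (chromosome 3, 107517448 to 107518260). The next were in an untranslated region of Inpp5f (chromosome 7, 128690375 to 128690927, fold 8.23) and in intergenic sequence 178 kb from the start of Rapgef2 (chromosome 3, 78967052 to 78967455, fold 8.08). The strongest in replicate 2 alone lay in exons of Arhgap33 (chromosome 7, 30531416 to 30531764, fold 6.60) and, 0.306 kb from its start, Pik3r2 (chromosome 8, 70769812 to 70770127, fold 6.25). A further one lay just outside Crmp1, 0.234 kb from its start (chromosome 5, 37241565 to 37241848, fold 6.16). The lists differ in length, so a peak missing from one of them is not a measured difference between the pools.

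The replicated peaks lay mainly at gene starts. Of the 31087 replicated peaks on the numbered, X and Y chromosomes, 20528 (66.0%) overlapped the sequence within 1 kb of an annotated transcription start site. A further 5399 (17.4%) lay in introns, 4015 (12.9%) between genes and 1145 (3.68%) in other exons. The peaks at start sites were the strongest and widest, with a median fold of 7.40 and a median width of 849 bp, against 3.47 and 331 bp in introns and 3.67 and 373 bp between genes. Randomly placed peaks reached start sites in 8.71% of cases on average and in at most 9.13% (100 placements, one-sided permutation p = 0.0099, the smallest possible). The share was 89.5% among the upper 50% of replicated peaks by fold, and 44.9% and 52.2% in the own lists of replicates 1 and 2. All the replicated peaks were present with the same coordinates in the pooled list. A peak of each replicate's own list overlapped 26753 (86.1%) of them, while 4334 (13.9%) had an overlapping peak in at most 1 of the replicates, with a median fold of 3.18 against 5.88. Statements on the replicated list therefore rest in part on peaks without a call in both pools.

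A replicated peak lay within 1 kb of a start site in 13803 of 21938 protein-coding genes (62.9%, exact 95% binomial interval 62.3% to 63.6%, over genes). The replicates' own lists marked 65.8% and 63.3% of the genes, an SD of 1.77 percentage points (n = 2). They gave the same answer, marked or not marked, for 95.4% of genes. Replicate 1 alone marked 777 genes and replicate 2 alone marked 228. Of the 13803 genes, 13562 (98.3%) were marked in both replicates' own lists.

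The mark was spread unevenly around the 5'-most annotated start of genes, mostly on its transcribed side. Other annotated starts of the same gene were not left out. Peaks at them count as downstream coverage, and no alternative changed the start used. In 6850 marked genes without another gene's start within 5 kb, replicated peaks covered 1016 ± 491 bp of the 2 kb downstream of the start and 367 ± 355 bp of the 2 kb upstream (mean ± SD over genes). The difference was 649 bp and 91.3% of the genes had more coverage downstream (two-sided permutation test over genes, p = 1e-05, the smallest that 100000 resamples can give). At the start itself 72.2% of these genes were covered. The share was highest 250 bp downstream, at 91.4%, and at 1000 bp it was 47.5% downstream and 7.40% upstream. The difference was 636 bp and 592 bp with the lists of replicates 1 and 2.

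**Figure D2:**
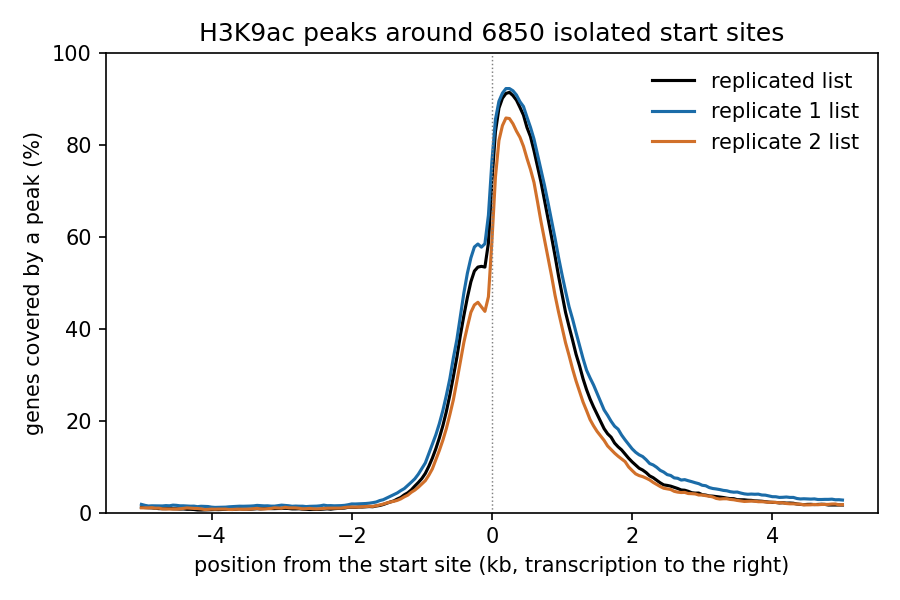
Share of 6850 marked protein-coding genes whose sequence was covered by a replicated peak (y axis, percent). The x axis gives the distance from the 5'-most transcription start (kb, negative values upstream). Further lines show coverage by each replicate's own list. Coverage by replicated peaks was highest at 250 bp downstream (91.4%), and at 1000 bp it was 47.5% downstream and 7.40% upstream.

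The 10 genes with the strongest promoter peaks had folds between 33.5 and 36.9. Top1, which encodes DNA topoisomerase I (ENSMUSG00000070544.6, chromosome 2, 160645888 to 160722764), had the highest fold at its start, 36.9, with 35.4 ± 3.96 in the replicates' lists (SD, n = 2). It was followed by Kmt5b, a histone H4 lysine 20 methyltransferase gene, at 36.6 (34.4 ± 8.87). Arid1a, a subunit of the SWI/SNF remodelling complex, Dbn1, which encodes the actin-binding protein drebrin, and Mex3b, an RNA-binding protein gene, each had 34.9. Phc2, a Polycomb group gene, had 34.7, Rbm39, a splicing factor gene, 34.5, and Marcksl1, a MARCKS family gene, 34.4. Ddx6, an RNA helicase gene, had 34.0, and Actg1, the gene of cytoplasmic gamma-actin, 33.5. The SD over the replicates reached 10.6 for Mex3b, which exceeded the gaps between these 10 genes. It includes a difference in scale between the lists, whose median folds over 26753 shared regions were 6.96 and 5.37. The order of the 10 genes is not resolved, since Top1 had the lowest of their folds in replicate 1 (32.6) and the highest in replicate 2 (38.2).

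The 10 genes with the widest marked domains were Hox genes, POU-domain genes and 5730596B20Rik. With peaks joined over gaps of up to 1 kb, the widest covered Hoxb2 to Hoxb6 and spanned 56350 bp (chromosome 11, 96299061 to 96355410). The next was at Pou3f3, a POU-domain transcription factor gene, with 30440 bp (chromosome 1, 42684116 to 42714555) and a fold of 25.2 at its start (24.5 ± 8.56, SD, n = 2). A domain of 25000 bp covered Hoxa1, Hoxa2 and the neighbouring 5730596B20Rik (chromosome 6, 52156532 to 52181531). Pou3f2, the partner of Pou3f3 in neural development, had 22420 bp (chromosome 4, 22476853 to 22499272). With gaps of up to 500 bp, 7 of these 10 genes stayed among the 10 widest, and with 3 kb 9 did.

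Marked promoters were rich in CpG dinucleotides. The median ratio of observed to expected CpG within 1 kb of the start was 0.612 in marked genes (interquartile range 0.482 to 0.724) and 0.175 in unmarked genes (0.117 to 0.263). The difference of 0.436 had a two-sided permutation p of 1e-05 over genes, the smallest possible. In the 10% of genes with the lowest ratio 3.46% were marked, and in the 10% with the highest ratio 98.4% were. Because of this dependence, each gene list is compared below both with all other protein-coding genes and with random lists matched on this ratio. The ratio was read at the 5'-most start only, whereas a peak at any start marks a gene. The number of annotated starts was not matched, for marking or for breadth, which was taken at the start with the most coverage.

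The Hox genes, which specify position along the body axis, divided by their order in the clusters. All 12 genes of groups 1 to 4, the groups that pattern the hindbrain, were marked, as were 9 of 11 genes of groups 5 to 8 and 1 of 16 of groups 9 to 13. The highest folds were at Hoxa2 (21.7, with 20.5 ± 3.37 in the replicates' lists, SD, n = 2), which patterns rhombomeres, and at Hoxb2 (20.7, 21.3 ± 4.63). Hoxb3 had 17.5, Hoxb4 13.7, Hoxd3 13.05, Hoxa4 12.7, Hoxa1 12.2 and Hoxc4 10.1. Hoxd4 (7.57, a peak that also reached the start of Gm28230), Hoxd1 (4.84), Hoxa3 (4.75) and Hoxb1 (4.15) had weaker peaks. In groups 5 to 8, Hoxa5 had 10.3, Hoxc5 9.35 and Hoxb5 5.72, and Hoxa6 and Hoxc8 had no replicated peak. The only marked gene of groups 9 to 13 was Hoxb9, with a fold of 3.76 (3.72 ± 0.0402). The own list of replicate 1 marked 2 of the 16 and that of replicate 2 marked 3, with Hoxd12 added in the first and Hoxa13 and Hoxb13 in the second. Peaks covered a median of 7528 bp within 5 kb of the start in groups 1 to 4 and 3844 bp in groups 5 to 8, against 1554 bp in other marked genes (permutation test over genes, adjusted p = 6e-05 for both). In these clusters that window can reach peaks at neighbouring Hox genes, and Hoxa6, without a replicated peak at a start, had 2211 bp. The median fold of groups 5 to 8, 5.19, was below other marked genes (adjusted permutation p = 0.0119). Against all other protein-coding genes, groups 1 to 4 were marked more often and groups 9 to 13 less often (Fisher's exact test, adjusted p = 0.00810 and 2.38e-05), and groups 5 to 8 did not pass the threshold (adjusted exact p = 0.230). CpG-matched lists were marked at 73.8%, 90.4% and 93.7%, and against them the calls for groups 1 to 4 and 9 to 13 held (adjusted permutation p = 0.0131 and 0.0008) and groups 5 to 8 again did not pass (adjusted permutation p = 0.5997). The difference between groups 1 to 4 and groups 9 to 13 was 93.8 percentage points (two-sided Fisher's exact test over genes, p = 4.27e-07). Neighbouring Hox genes share domains and are not independent, so these p-values are too small. When only the 5'-most annotated start of each gene was counted, groups 1 to 4 had 9 of 12 and the difference was 68.8 points (Fisher's exact p = 0.000273), while the call for groups 1 to 4 against all other genes ended (adjusted exact p = 0.418), as it did with the upper 50% of peaks by fold (adjusted exact p = 0.290). The breadth of groups 5 to 8 exceeded other marked genes by 2290 bp, by 1367 bp with replicate 2's list alone, and was not past the threshold within 2 kb of the start (adjusted permutation p = 0.536).

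The mark covered different parts of the 4 clusters, in which peaks were counted over the span of the genes and 10 kb either side. In the Hoxb cluster (genes at chromosome 11, 96194316 to 96368256), 33 replicated peaks covered 55932 bp and 9 of 10 genes were marked. The Hoxa cluster (genes at chromosome 6, 52155590 to 52260880) had 26 peaks over 36801 bp and 6 of 11 genes marked. The Hoxc cluster (genes at chromosome 15, 102921103 to 103036852) had 18 peaks over 17778 bp and 3 of 9 genes marked, and its widest domain spanned 10455 bp. The Hoxd cluster (genes at chromosome 2, 74668310 to 74765142) had 8 peaks over 26670 bp and 4 of 9 genes marked, with a widest domain of 18263 bp.

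**Figure D3:**
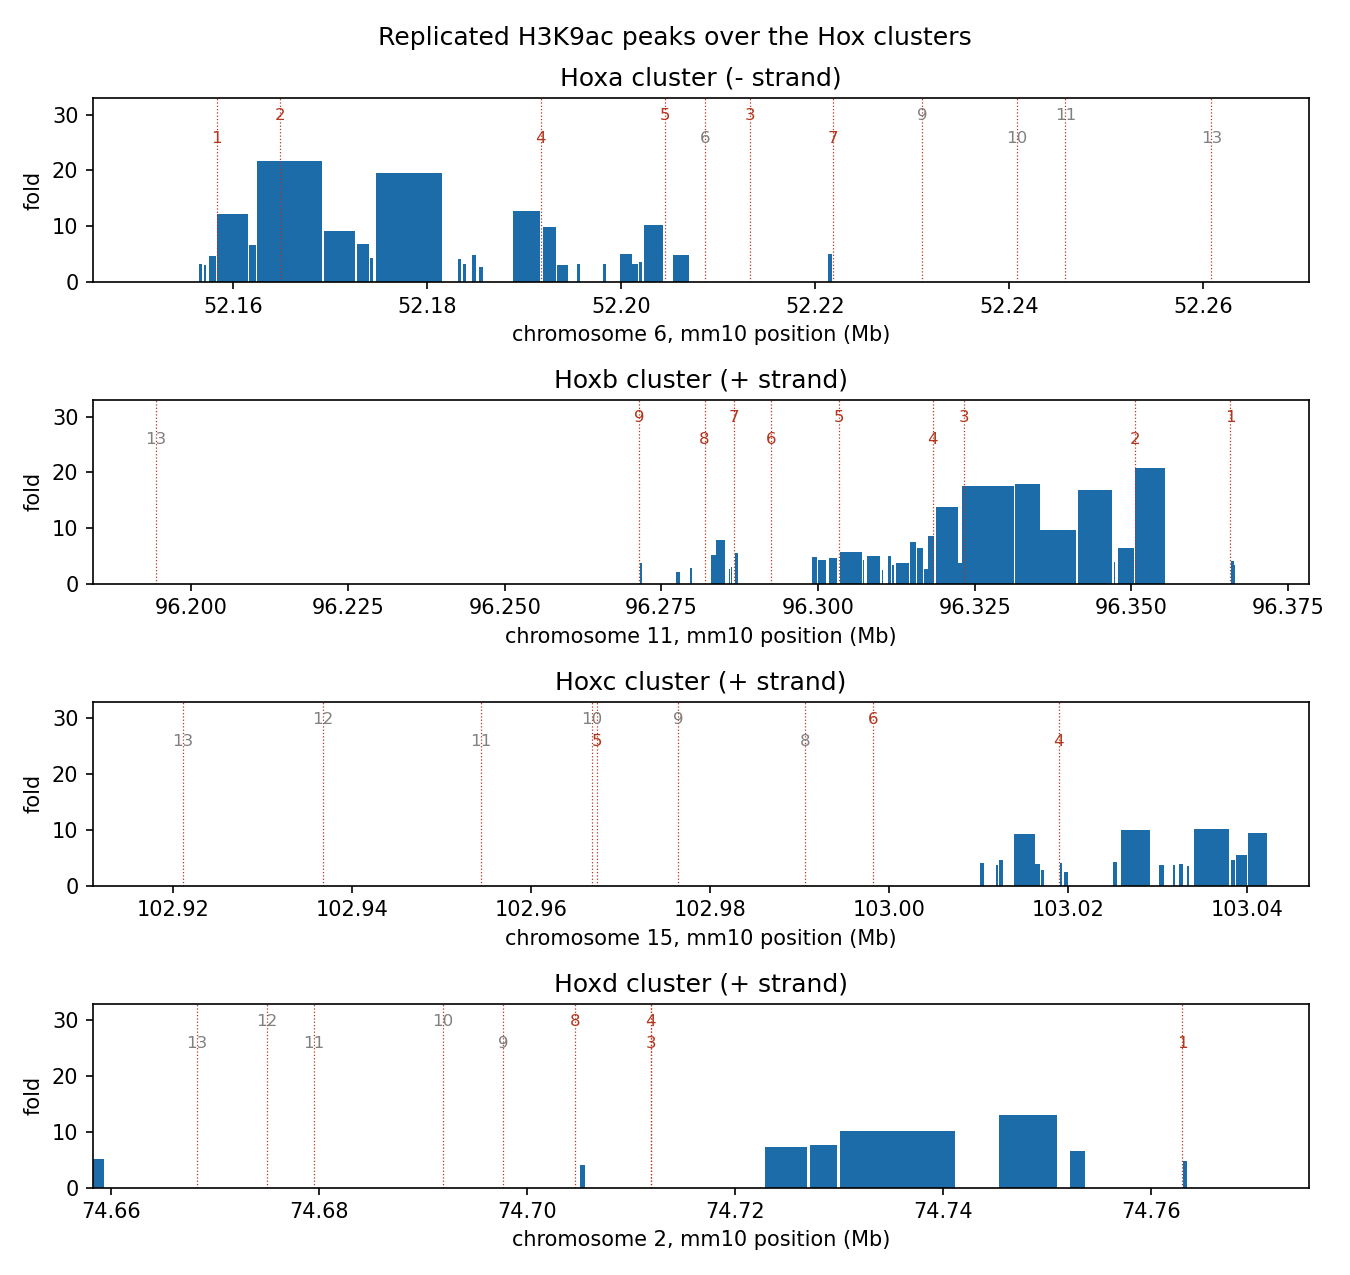
Replicated peaks over the 4 Hox clusters, with position in the mm10 build on the x axis, the authors' fold enrichment on the y axis and a dotted line at the 5'-most start of each gene. Red numbers mark genes with a peak within 1 kb of any annotated start; a marked start can therefore lie away from the dotted line, and 12 of 12 genes of groups 1 to 4 but 1 of 16 of groups 9 to 13 are red.

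Most genes of hindbrain patterning and all neural progenitor genes were marked, with broad coverage that several lists below shared. Of the genes that pattern the hindbrain and its rhombomeres, 25 of 27 were marked, led by Meis1 (fold 33.4, 31.3 ± 7.48, SD, n = 2) and Meis2 (25.7), which encode partners of Hox proteins, and by the nuclear receptor gene Nr2f1 (28.2). Cyp26c1, a retinoic acid hydroxylase gene, and Hnf1b had no replicated peak. All 20 neural progenitor genes were marked, with the highest folds at Msi1, an RNA-binding protein of neural stem cells (23.4, 22.4 ± 6.49), at Cdh2, which encodes N-cadherin (20.6), and at the Notch target Hes5 (20.0), whose peak also reached the start of Pank4. Both lists were marked more often than other protein-coding genes, of which about 63% were marked (Fisher's exact test, adjusted over the 20 lists, p = 0.00161 and p = 0.000198). Within 5 kb of the start, peaks covered a median of 4473 bp in the patterning genes and 5118 bp in the progenitor genes, against 1553 bp in other marked genes (permutation test over genes, adjusted p = 6e-05 for both). The median fold was 15.8 in the progenitor genes, above the 10.5 of other marked genes (permutation test, adjusted p = 0.003), and that of the patterning genes equalled the other marked genes at 10.5 (adjusted permutation p = 1). Random lists matched on CpG were marked at 83.5% and 89.1%, and against them the marking passed no threshold (adjusted permutation p = 0.185 and 0.0714). With the upper 50% of peaks by fold, the patterning genes also lost the marking call, at 19.02 percentage points above other genes in place of 29.7.

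Genes of the dorsoventral progenitor domains had weak peaks and, within 5 kb of the start, wide coverage. Of 26 such genes 20 were marked, among them Irx5 (fold 21.1, 21.4 ± 6.80, SD, n = 2), the proneural gene Ascl1 (14.4) and Pax7, a factor of dorsal progenitors (10.1). Dbx2 and Foxa2, a floor plate gene, had no replicated peak, although Foxa2 was marked in both replicates' own lists, with 3.18 ± 0.416. The median fold was 5.62, below other marked genes (permutation test, adjusted p = 0.000840), and the median coverage 2562 bp was above them (adjusted p = 0.000667). The breadth call was lost within 2 kb of the start (adjusted permutation p = 0.249) and with replicate 1's list alone (adjusted permutation p = 0.0682), and the difference of 1007.5 bp was 505 bp and 585.5 bp with the lists of replicates 1 and 2. The marking call depended on the list and background used. The 76.9% marked did not pass the threshold against other genes (adjusted exact p = 0.172), fell short of the 92.6% of CpG-matched lists (adjusted permutation p = 0.0195), and passed the threshold above other genes with either replicate's own list (adjusted exact p = 0.0170 for replicate 1 and 0.0352 for replicate 2).

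The listed genes shared by most neurons were all marked, and those listed for hindbrain neuron subtypes, some of them shared by broad classes of neurons, had weak peaks. All 20 pan-neuronal genes were marked (adjusted exact p = 0.000198), and they were also above CpG-matched lists, of which 71.1% were marked (adjusted permutation p = 0.0008). Elavl3, an RNA-binding protein of postmitotic neurons, had a fold of 20.0 (19.1 ± 8.86, SD, n = 2), Ncam1, a neural cell adhesion molecule gene, 18.8, and Tubb3, which encodes a neuronal tubulin, 17.1. Peaks covered a median of 2569 bp in pan-neuronal genes and 2583 bp in the subtype markers below, both above the 1553 bp of other marked genes (adjusted permutation p = 0.000412 and 0.0003), although the latter call was lost within 2 kb of the start (adjusted permutation p = 0.945). The difference for the subtype markers was 1030 bp, and 1814 bp with replicate 1's list alone. Of 31 markers of hindbrain neuron subtypes 25 were marked (adjusted exact p = 0.0520), with a median fold of 5.02, below other marked genes (permutation test, adjusted p = 7.5e-05). Nhlh2 had 14.9, and the LIM homeobox genes Lhx5 and Lhx1 had 9.94 and 9.72. Chat, which encodes the acetylcholine-synthesising enzyme, and Fev, a serotonergic factor, had no replicated peak. Counting replicate 1's list alone, 28 of the 31 were marked (adjusted exact p = 0.00557), and with replicate 2's list alone 23 were (adjusted exact p = 0.293). CpG-matched lists were marked at 82.2%, slightly above the 80.6% of these genes (adjusted permutation p = 0.976).

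Genes of neighbouring brain regions were marked less often than their CpG content would give. Of 27 transcription factors of the forebrain and midbrain 13 (48.1%) were marked, against 89.9% in CpG-matched lists (adjusted permutation p = 0.0008) and 62.9% of other genes (Fisher's exact test, adjusted p = 0.136). Their peaks were weak and narrow, with a median fold of 3.67 (permutation test, adjusted p = 7.5e-05) and 543 bp covered (adjusted p = 0.00015). The strongest were Otx1 (6.89, 6.53 ± 1.37, SD, n = 2), Gsx1 (5.70) and Lhx2 (4.56). Arx and Emx2, both forebrain genes, had no replicated peak. The call against all other genes was reached at a window of 500 bp and at a -log10 q of 2 or more, with differences of -21.5 and -21.3 percentage points. With replicate 1's list alone 17 of the 27 were marked, and the difference moved from -14.8 to -2.88 points.

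Lists of other cell types that the dissected tissue could hold ranged from mostly marked to mostly unmarked. Of 23 mesenchyme and neural crest genes 20 were marked (adjusted exact p = 0.0222), with the neural crest factors Tfap2a (fold 10.5, 10.5 ± 2.63, SD, n = 2) and Tfap2b (8.93) and the mesenchymal homeobox gene Prrx2 (7.50) highest. Dcn and Lum, which encode matrix proteoglycans, had no replicated peak. The median fold of this list was 4.54, below other marked genes (permutation test, adjusted p = 7.5e-05). Of 19 endothelial genes 9 were marked (adjusted exact p = 0.172, and adjusted permutation p = 0.128 against the 63.7% of CpG-matched lists), with Fli1 at 10.3, Egfl7 at 7.27 and Kdr, a receptor of vascular endothelial growth factor, at 6.31, and no replicated peak at Cdh5 and Emcn. The Egfl7 peak also reached the start of Gm20532. The marked endothelial genes had a median fold of 4.85 and 636 bp covered, both below other marked genes (adjusted permutation p = 0.00829 and 0.0018). With replicate 1's list alone 12 of the 19 were marked, and the difference from other genes moved from -15.6 to -2.68 percentage points. Of 20 blood and microglia genes 3 were marked (adjusted exact p = 5.67e-05), and these were the erythroid genes Klf1 (8.59), Gypa (4.83) and Epor (3.29). Aif1 and Alas2 had no replicated peak. The call for mesenchyme and neural crest was lost with either replicate's own list (adjusted exact p = 0.0561 for replicate 1 and 0.108 for replicate 2) and against the 72.4% of CpG-matched lists (adjusted permutation p = 0.0663). That for blood and microglia was lost against the 22.5% of CpG-matched lists (adjusted permutation p = 0.5997).

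Genes of later or unrelated tissues were mostly unmarked. Of 1135 olfactory receptor genes 2 (0.176%) were marked, Olfr94 (fold 6.05) and Olfr658 (3.29), which was below both other genes and the 8.11% of CpG-matched lists (adjusted permutation p = 0.0008 for the latter), and Olfr1 and Olfr10 were among those without a replicated peak. Of 17 germline genes 2 were marked, Brdt (7.74) and Dazl (5.87), against 79.5% of CpG-matched lists (adjusted permutation p = 0.0008), and Asz1 and Ddx4 had no replicated peak. The Brdt peak (chromosome 5, 107359537 to 107360360) lay inside the gene, whose 5'-most start is at 107331159. Of 29 genes of differentiated non-neural tissues 6 were marked (adjusted exact p = 2.81e-05). The strongest of them was Sftpc, a lung surfactant gene (19.6), which only replicate 2's own list marked. Its peak (chromosome 14, 70518890 to 70521319) spanned the 3' end of Sftpc, whose 5'-most start is at 70524081. The same peak also reached the start of the neighbouring Bmp1. Krt1 (13.2) and Actn2 (5.49) followed, and Acta1 and Ahsg had no replicated peak. The Krt1 peak (chromosome 15, 101845774 to 101846653) also lay near the 3' end of the gene, whose 5'-most start is at 101850794. Of 15 mature glia genes 4 were marked (adjusted exact p = 0.00817), including the glutamate transporter gene Slc1a2 (13.1) and the myelin genes Mbp (7.88) and Cnp (5.53), but not Aldh1l1 and Aqp4, which had no replicated peak. Neither of these last calls held against CpG-matched lists, which were marked at 37.6% and 40.9% (adjusted permutation p = 0.0531 and 0.286). The call for glia was also lost with the own lists of replicates 1 (adjusted exact p = 0.0620) and 2 (adjusted p = 0.130).

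Ribosomal protein, housekeeping, acetyltransferase and deacetylase, and cell cycle genes were almost completely marked. Of 82 cytoplasmic ribosomal protein genes 80 were marked (adjusted exact p = 7.5e-13), with a median fold of 16.7, above other marked genes (permutation test, adjusted p = 7.5e-05). Rpl32 had 27.9 (25.9 ± 5.75, SD, n = 2), Rpl13a 26.8 and Rpsa 26.7, and the only members without a replicated peak were the paralogs Rpl10l and Rpl39l. All 24 housekeeping genes were marked (adjusted exact p = 5.67e-05), including Eef1a1 (24.9), Ubc (20.3, a peak that also reached the start of Gm10382) and Ywhaz (20.1). So were all 22 lysine acetyltransferase and deacetylase genes (adjusted exact p = 0.000133), with Ep300 at 26.8, Hdac7 at 23.3 and Hdac2 at 23.1 and a median fold of 15.4 (permutation test, adjusted p = 0.003), 4.92 above other marked genes and 3.21 above them with replicate 2's list alone. All 22 cell cycle genes were marked (adjusted exact p = 0.000133), including Mcm4 (13.6, a peak that also reached the start of Prkdc), Mki67 (13.5) and Mcm6 (13.5). Coverage was above other marked genes in ribosomal protein genes (median 2144.5 bp, adjusted permutation p = 6e-05) and cell cycle genes (2145.5 bp, adjusted permutation p = 0.0214), the latter not within 2 kb of the start (adjusted permutation p = 0.0608). Against CpG-matched lists the first 3 of these marking calls held (adjusted permutation p = 0.0344, 0.0344 and 0.00333), and that for cell cycle genes did not (94.1% marked, adjusted p = 0.579). This matching does not cover peaks at other starts, such as that of Hdac7 (chromosome 15, 97830576 to 97832271, 5'-most start at 97844502). With 5'-most starts only, acetyltransferase and deacetylase genes were 22.8 percentage points above other genes (adjusted exact p = 0.0439), in place of 37.1.

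**Figure D4:**
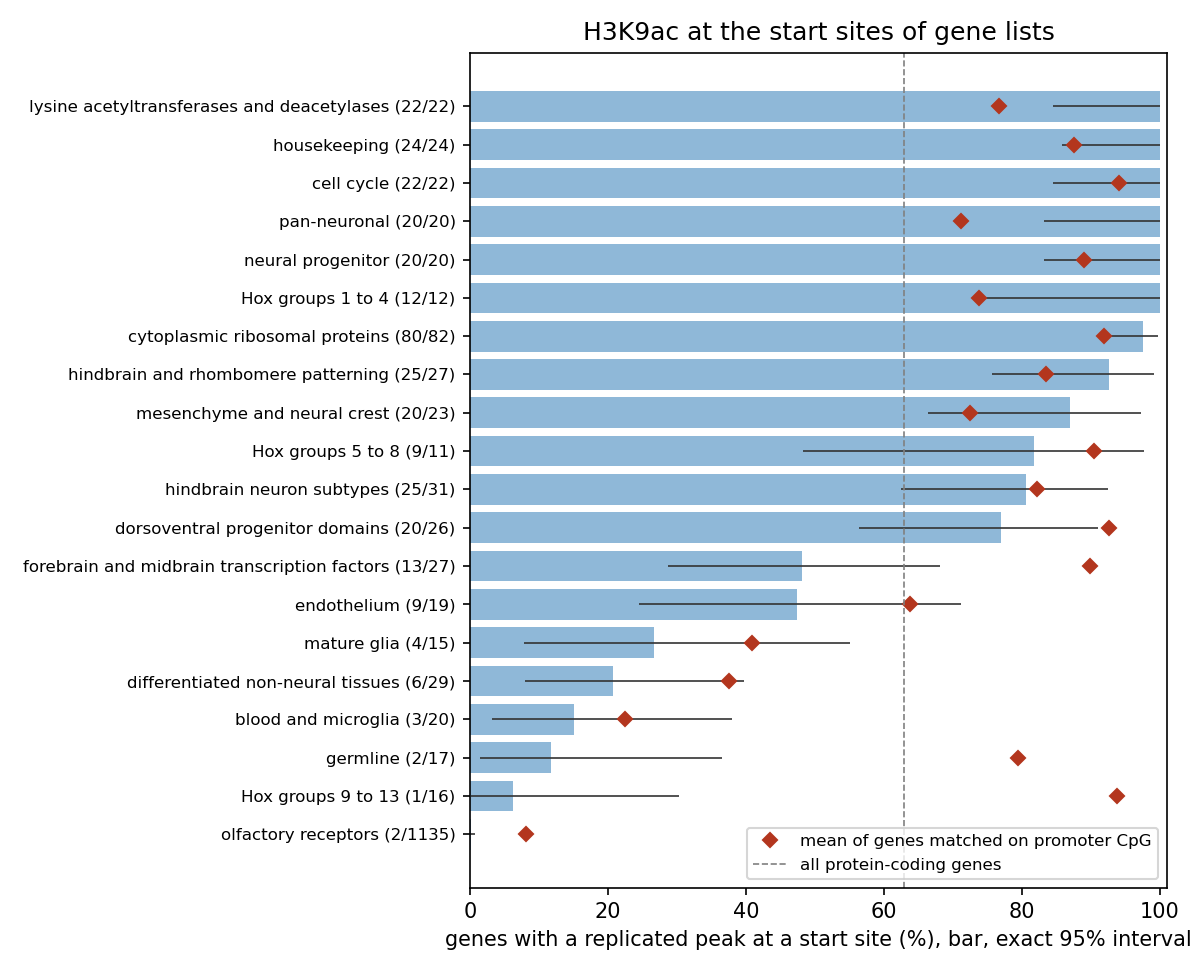
Share of genes with a replicated peak at a start site (percent) in each of the 20 gene lists, with the number of genes and the share in CpG-matched random lists. Neural progenitor, pan-neuronal and housekeeping lists reached 100%, forebrain and midbrain factors 48.1% and olfactory receptors 0.176%.

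Genes of hindbrain patterning, neural progenitors and dorsoventral domains were more often the nearest gene of a distal peak than matched lists. Of the replicated peaks 6048 (19.5%) lay over 5 kb from every annotated start, with a median fold of 3.50. Among hindbrain patterning genes, 20 of 27 (74.1%) were the nearest gene of at least 1 such peak, against 23.5% in random lists matched on the length of sequence nearest to each gene (permutation test over genes, adjusted p = 0.00133). Pbx1, a Hox cofactor, had 13, Meis2 had 12, Nr2f1 had 8 and Pax2 had 6, of 77 nearest to this list in all. The shares were 55.0% against 19.1% for neural progenitor genes (adjusted permutation p = 0.00133), where Notch1 had 15 and Sox9 9, and 50% against 22.7% for dorsoventral genes (adjusted permutation p = 0.0210). Olfactory receptors were the nearest gene less often than matched lists, 0.529% against 5.81% (adjusted permutation p = 0.00133, with differences of -13.5 and -10.95 percentage points in the lists of replicates 1 and 2), and the other 16 lists did not pass the threshold. The dorsoventral call was lost with replicate 2's list alone (adjusted permutation p = 0.158). Ribosomal protein genes, at 14.6% against 7.25% (adjusted permutation p = 0.0688), passed the threshold only in alternatives, among them distal peaks over 10 kb from a start.

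The 5 strongest distal peaks lay near other genes. The highest had a fold of 21.1 and lay in intergenic sequence 16.0 kb from Cbx8, a Polycomb group gene (chromosome 11, 119056186 to 119057754). The next lay in an intron of AC165153.1, 184 kb from Foxn2 (chromosome 17, 88255536 to 88257209, fold 18.8). The others were intergenic, 16.1 kb from Pogz (chromosome 3, 94820973 to 94822057, fold 18.6), 5.93 kb from Zfp869 (chromosome 8, 69716347 to 69716951, fold 18.3) and 32.9 kb from Pum2 (chromosome 12, 8640776 to 8641722, fold 17.9). Nearest genes are by distance alone, and no contact between these peaks and the genes was measured.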

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

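The comparison of mesenchyme genes with CpG-matched genes, that of overlap with fold, that of mostly unique promoters and that of transcription factor families were chosen only after the result they bear on was seen. The tests of other cell types, of split domains and of repeated sequence were set before theirs.

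Peaks outside the chromosomes used in the report were found in the replicated list. There were 6 of them, on sequences not placed on a chromosome or not placed within one, and they are listed because no comparison uses these sequences. No level to expect there was available. The strongest had a fold of 10.4 (on a chromosome 4 sequence, 16089 to 17137), and the others had 6.04, 5.02, 3.18, 2.20 and 1.61. No gene was assigned to them.

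Mesenchyme and neural crest genes combined frequent marking with weak peaks. Promoter CpG content alone does not account for the weak peaks. The median fold of the marked members was -6.34 relative to marked genes matched on CpG content (adjusted permutation p = 0.0005). The frequent marking itself did not pass the threshold against CpG-matched lists (87.0% against 72.4%, adjusted permutation p = 0.0663). Weak peaks were not particular to this list. Median folds also lay below CpG-matched marked genes in neuron subtypes (5.02 against 10.7) and dorsoventral genes (5.62 against 11.7). So did Hox groups 5 to 8 (5.19 against 10.8), forebrain factors and endothelium. Progenitor, ribosomal protein, and acetyltransferase and deacetylase genes lay above their matched genes. Acetylated chromatin from other cells in the dissected tissue may contribute to the mesenchyme pattern, as a hypothesis. Of the genes such cells use most, Col1a2 (fold 4.26), Col3a1 (3.67, not marked in replicate 2's own list) and Col1a1 (2.67) had weak peaks, and the globin genes Hbb-y and Hba-a1 had no replicated peak. Whether the sequence of the globin promoters is unique in the genome was not measured, so their missing peaks do not show that blood cells were absent. Over the 35 CpG-poor members of the mesenchyme, endothelium and blood lists 25.7% were marked against 23.7% of matched genes (permutation p = 0.911), and the parts pointed apart, with 6 of 8 mesenchyme members marked against 27.7% expected (p = 0.00900 by permutation, unadjusted and looked at afterwards) but 1 of 8 endothelial and 2 of 19 blood members. This explanation and use of these genes by neural cells cannot be told apart with 1 tissue.

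Of the peaks of replicate 1, 29770 had no counterpart in replicate 2. The share overlapped differed by 61.3 percentage points or more between the strongest and the weakest 10% in both lists, but this follows from the low folds already seen in the unshared peaks, so whether they are weak peaks near the calling threshold stays open. Domains split into separate peaks also remain open for some of them, since 31.02% lay within 1 kb of a replicate 2 peak, against 5.91% of randomly placed ones. Depth is unknown, and no biological explanation was tested because both pools belong to 1 group.

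Among promoters in the upper 3 deciles of CpG content, 160 of 6581 (2.43%) had no replicated peak. Sequence that occurs more than once in the genome may account for some, since in 42 of the 160 (26.3%) fewer than 50% of 31-base words were unique, against 0 of 160 matched marked promoters (Fisher's exact p = 2.04e-14). It leaves the other 73.8%, whose words were mostly unique, although the read length is unknown. Outside the gene lists, members of developmental transcription factor families, taken by symbol, were 7.71 times as frequent among the unmarked promoters (17 of 139) as among the marked ones (99 of 6245, Fisher's exact p = 3.40e-10). A candidate explanation is that these genes are silent in the hindbrain at this age, which peak lists alone cannot show.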

How the results depend on the processing

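The restrictions to peaks overlapped in both replicates and to peaks of 1 gene only were chosen after seeing the data. The replicate overlaps, the share of peaks at start sites, the excess of coverage downstream, the CpG difference and the Hox comparison kept their direction and their side of the threshold under each alternative run for them. So did 177 of 220 values of single gene lists for marking, 83 of 90 for strength, 74 of 90 for breadth and 94 of 120 for distal peaks. The number of lists past the threshold for marking was 15, and 10 when matched on CpG. Of 750 folds of named genes under other settings, 667 moved by less than the spread between replicates and 83 by more. That spread includes the difference in scale between the replicates' lists. Differences below are in percentage points for marking and distal peaks, in fold for strength and in bp for breadth, list minus background. Unless a construction is named, the cause was not tested.

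The rank agreement was 0.844 by -log10 p. The share of genes marked was 55.1% with the upper 50% of peaks by fold, 59.1% with 5'-most starts only, and 51.5% with peaks of 1 gene only, where fewer peaks or starts can mark a gene, and 63.3% to 65.8% without 1 replicate.

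For marking, the upper 50% of peaks by fold gave 19.9 for Hox groups 1 to 4 and 19.02 for hindbrain patterning, both no longer past the threshold. It turned the sign for Hox groups 5 to 8 (-9.63), dorsoventral genes (-5.09), neuron subtypes (-9.94) and mesenchyme (-16.0), and brought forebrain factors (-47.7) and endothelium (-34.1) past it. With 5'-most starts only the values were 15.9 for Hox groups 1 to 4 and 10.5 for mesenchyme, both lost, -4.55 for Hox groups 5 to 8 and -22.1 for forebrain factors, now past the threshold. Forebrain factors also passed at 500 bp (-21.5), at a -log10 q of 2 (-21.3) and with peaks overlapped in both replicates (-24.6), where endothelium passed too (-24.8). Mesenchyme was lost in the same settings (16.0, 16.3 and 21.0025). Neuron subtypes passed at 2 kb (20.2) and with the pooled list (23.1), as dorsoventral genes did with the pooled list (20.6). With peaks of 1 gene only, dorsoventral genes (25.4) and neuron subtypes (25.9) passed and mature glia did not (-24.9). Without 1 replicate, dorsoventral genes gave 21.3 to 22.6, neuron subtypes 10.9 to 24.5, forebrain factors -15.2 to -2.88, endothelium -10.7 to -2.68, mature glia -25.9 to -23.4 and mesenchyme 19.3 to 21.1.

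Matching on CpG, which changes the background, turned the marking of Hox groups 5 to 8 (-8.58), dorsoventral genes (-15.7) and neuron subtypes (-1.52). It ended the call for hindbrain patterning (9.10), progenitors (10.9), mesenchyme (14.5), blood (-7.51), mature glia (-14.2), non-neural tissues (-16.9) and cell cycle (5.95), and brought forebrain factors (-41.8) past the threshold. For strength it turned pan-neuronal (0.290) and cell cycle genes (-0.215), neither called, and ended the call for non-neural tissues (-2.80). That call was also lost by -log10 p (-18.7 in -log10 units). Without 1 replicate the strength of housekeeping genes was 2.80 to 3.80, past the threshold, and that of pan-neuronal genes -0.367 to 0.0973.

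For breadth, the pooled list gave 6 for mesenchyme, against -230.5, and brought non-neural tissues (-707), housekeeping (559) and acetyltransferases and deacetylases (603) past the threshold. The last also passed when matched on CpG (559) and at 2 kb (460). Non-neural tissues passed with peaks overlapped in both replicates (-785) and at 2 kb (-712). At 2 kb, which caps the coverage, the call was lost for Hox groups 5 to 8 (232), dorsoventral genes (280), neuron subtypes (15) and cell cycle (427). Without 1 replicate the ranges were -984 to -696 for non-neural tissues, 505 to 586 for dorsoventral genes and 412 to 667 for housekeeping.

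For distal peaks over 2 kb from a start, neuron subtypes passed (24.2) and the sign turned for Hox groups 5 to 8 (22.4), pan-neuronal genes (4.49), mature glia (18.8) and acetyltransferases and deacetylases (-1.71). Over 10 kb, ribosomal genes passed (7.47), and the sign turned for neuron subtypes (-2.66) and acetyltransferases and deacetylases (-2.61). With peaks overlapped in both replicates ribosomal genes passed (8.70) and non-neural tissues turned (-4.35). Without matching on territory, mesenchyme passed (21.5), and the sign turned for Hox groups 1 to 4 (-4.93), pan-neuronal genes (1.74), forebrain factors (1.55), mature glia (0.0687) and non-neural tissues (-2.92). Without 1 replicate the ranges were -1.84 to 5.53 for blood, 9.38 to 15.8 for ribosomal genes, -4.34 to 2.38 for non-neural tissues, 20.0 to 32.9 for dorsoventral genes, -4.97 to 5.61 for forebrain factors, -0.998 to 2.69 for housekeeping, 12.998 to 29.4 for mature glia and 6.61 to 19.7 for pan-neuronal genes.

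No paired analysis was possible because there was only 1 group. Depth is unknown, so its limits on weak peaks could not be measured.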

Other observations

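The test of the X chromosome and the ranking by distal peaks were chosen after the data were seen.

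The gene with the most distal peaks was Gse1, which encodes a coiled-coil protein (chromosome 8, 120228456 to 120581390). It was the nearest gene of 68 replicated distal peaks, all of them inside the gene, which together covered 27.1 kb over a span of 302 kb. Their median fold was 3.50. The replicates' own lists held 120 and 82 such peaks. In the replicated list the next genes were Cstad with 26 and Tpra1 with 25. That order did not hold in replicate 1's own list, where Gm26897 had 57 and Cstad 39. Nor did it hold in replicate 2's own list, where Tpra1 had 37 and Cstad 35. Genes were ranked by count alone and no test was run.

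Genes on the X chromosome were marked less often than others. Of 948 protein-coding X genes 415 (43.8%) had a replicated peak at a start site, against 64.3% of genes on the autosomes and 52.9% of genes matched on CpG content (permutation p = 0.0002, the smallest that 10000 random lists can give). On the Y chromosome 2 of 183 genes were marked. Sequence that occurs more than once in the genome was not measured for X and Y genes as a set, and no cause of either low share was tested. Both pools held embryos of both sexes, and the sexes were not compared.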
